A study of Homo sapiens and Homo sapiens
Mus musculus with 13 samples.

How the data were processed

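The study measured gene expression in single MSCs on and off nanovials and, in SEC-seq, the VEGF-A captured around each cell. Reads were processed with Cell Ranger and Seurat against the builds GRCh38 and GRCm38, per the submitters' processing notes, which give neither versions nor the role of each. The 5 deposited tables held natural log values: in the 4 human tables each value was the natural log of 1 plus the counts per 10000 counts of the cell, per the values. The authors' deposited cell metadata held mRNA counts, detected genes and counts of the VEGF-A or nanovial barcode per cell. For the mixed-species library the deposited metadata held human and mouse signal per cell that had been scaled before it was summed, so it was not used as counts, and its expression rows carried numbers without gene names. The authors' deposited ratio of human to mouse signal and ratio of both nanovial barcodes were used as given, as were the other text columns the authors deposited (condition, species and cluster of each cell).

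Whole counts were recovered from the human tables by inverting the log and multiplying by the cell total over 10000; 100% of values lay within 0.01 of a whole number. Total mRNA counts were 35648402, 29977606 and 36317317 in the suspended, sorted and nanovial-loaded libraries, 12444780 and 16481616 in the pooled normoxic and hypoxic cells, and 77173553, 175259357 and 90359518 in SEC-seq normoxic replicates 1 and 2 and the hypoxic library. All deposited cells were kept in the main results. Doublets of 1 cell line cannot be seen in these tables and no doublet caller was run. Older gene symbols were replaced by current ones with a RefSeq gene table (assembly GRCh38.p14) where the match was unambiguous: 488, 490, 533 and 499 genes in the suspended, pooled, SEC-seq and SEC-seq replicate 2 tables. The SEC-seq tables shared 15855 genes and the tables of the hypoxia comparison 14648.

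The unit of replication was the library or experiment, never the cell. The labels do not say whether libraries came from separate cultures, so p-values rest on the spread between these libraries, shared in part across genes. Technical spread alone can produce it. Tables were normalised separately, so tests used differences within a table or library. For secretion, cells of each of the 3 SEC-seq libraries in the top and bottom 25% of the VEGF-A barcode (641, 563 and 735 cells per quartile) were compared by the difference of log2(mean counts per 10000 + 0.01). For hypoxia, the 2 differences were those of the pooled library and of SEC-seq hypoxic against normoxic replicate 1. Genes with a mean of at least 0.05 per 10000 were tested with limma 3.58.1 (R 4.3.3, intercept only, eBayes with a trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates changes of low genes. Every SE and p-value of a gene is moderated: limma draws its spread toward that of genes of similar level. With 2 or 3 differences per gene, these can be far smaller than the gene's own differences would give. Whether the secretion difference differed between conditions was tested in the same way, with 1 residual degree of freedom. Camera tested 20 of 24 gene lists at a preset correlation of 0.01 and at an estimated one. With 2 or 3 differences per gene the estimate is itself uncertain, so a list that fails there may still differ. The endothelial, haematopoietic, adipocyte and epithelial lists had too few measured genes. Comparisons with 1 library per group had no test: they give values, exact Poisson intervals of summed counts, exact binomial intervals of shares (both at 95%) and the percentile of a list's median among 10000 random lists matched on expression. Analyses in Python 3.11.15 used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

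The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. Named genes were a fixed panel of single genes, the 10 largest rises and 10 largest falls among called genes with the same sign in every library or experiment, 2 to 4 members of each list with the largest change in the direction of its median and, where no test was possible, the 10 largest ratios each way among genes with a mean of at least 0.5 per 10000 and separate Poisson intervals; a few genes that met this rule are not reported here. Simulated data with 200 changed genes were used to check the fits: with 3 libraries and 9644 genes, 97% of log2 changes of 0.5 and 100% of changes of 1 were recovered with 10 false calls, and with 2 experiments and 9402 genes 87% and 100% were recovered with 1 false call. The simulation added noise with an SD of 0.1 to each log2 difference, independent between genes, beside counting error. Real genes can vary more, as PLCG2 did by secretion (-2.76, -1.11 and -0.78), and can shift together. These rates therefore check the fits and do not describe the real calls. Alternatives were pseudocounts of 0.1, no filter or a filter of 0.5, edgeR 4.0.16 quasi-likelihood tests on the recovered counts, means of the log values, 10% tails and a median split of the barcode, quartiles within 10 bins of mRNA counts, leaving out each library, other SEC-seq controls, and other thresholds for mixed species. Alternatives chosen after seeing the data were leaving out 241 normoxic cells with the barcode prefix of hypoxic cells, cells with a mitochondrial share under 10%, bins of mitochondrial share, leaving out the authors' cluster of highest median barcode, the other SEC-seq controls for hypoxia lists, and a list of ribosome biogenesis genes.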

Results

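Immortalised human adipose-derived mesenchymal stromal cells (MSCs, line ATCC SCRC-4000) were profiled by 3′ single-cell RNA sequencing on the 10x Chromium platform, either in suspension or bound to nanovials. Nanovials are gelatin-coated hydrogel particles that hold a cell and capture the protein it secretes. In secretion-encoded sequencing (SEC-seq), captured VEGF-A is stained with an oligonucleotide-barcoded antibody, so that a VEGF-A barcode count and a transcriptome are read from the same cell. By the labels, cells were loaded for 2 h, secreted for 12 h and were stained for 30 min. The labels give these steps for the suspended samples too, and it is not clear which applied to cells never loaded on nanovials. Cells called hypoxic by the labels received 500 µM deferoxamine, an iron chelator that stabilises the hypoxia-inducible factors (HIF) by inhibiting the enzymes that mark them for degradation. The series has 13 samples, and each condition has 1 library except SEC-seq under normoxia, which has 2.

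The suspended, suspended and sorted, and nanovial-loaded libraries held 3559, 3297 and 2391 cells, with medians of 9482, 8504 and 14053 mRNA counts per cell. A library that pooled normoxic and hypoxic nanovials held 865 cells called normoxic (median 13648 counts) and 1249 called hypoxic (median 12447 counts). SEC-seq held 2566 cells in normoxic replicate 1, 2254 in normoxic replicate 2 and 2943 in the hypoxic library, with medians of 27830, 72714 and 27424 mRNA counts. Surface markers of MSCs summed to between 52.1 counts per 10000, in pooled normoxic cells, and 77.6, in hypoxic SEC-seq cells. The highest member was CD63 (18.5 to 27.7) except in hypoxic SEC-seq cells, where it was ITGB1 (27.2). These sums cover 17 or 18 measured genes and those of the other cell types at most 8, so their sizes cannot be set against each other. Of the other cell types, epithelial markers summed to between 0.391 and 1.53 counts per 10000, the highest in suspended and sorted cells (KRT8 at 1.13 and 1.09). Pericyte and smooth muscle markers summed to between 0.581 and 1.53 and endothelial markers to between 0.0587 and 0.219. Among haematopoietic markers CD68 was the most abundant in every library, at 0.169 to 0.362 counts per 10000, and among adipocyte markers PPARG, at 0.0619 to 0.310.

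How often a droplet held RNA of more than 1 cell was examined by sequencing nanovials loaded with MSCs and with mouse embryonic fibroblasts together. By the authors' deposited call, 2821 of 6296 cells were human (44.8%), 2960 were mouse (47.0%) and 515 were mixed (8.18%, exact binomial 95% interval 7.51 to 8.88). The call divided cells at about a 2-fold excess of either species, since human cells had a human-to-mouse ratio of at least 2.00, mixed cells one of at most 1.99 and mouse cells one of at most 0.498. The median human share was 96.6% in cells called human, 46.9% in mixed cells and 0.667% in mouse cells. For this share the unnamed rows were cut into a human block (14735 rows) and a mouse block (14790). The cut was placed to match which rows were higher in cells called human or mouse, and 29474 of 29525 rows agreed. Counts were recovered by dividing by each cell's smallest value. Shares on recovered counts therefore rest in part on the call. Requiring 90% of a cell's deposited, scaled signal from a single species raised the mixed share to 25.9%, and requiring 80% gave 15.9%; on recovered counts these shares were 19.97% and 12.5%. Cells of the same species that share a nanovial or droplet do not show as mixed, so the mixed share is not the full rate of shared droplets. The sample title names pooled MSC- and fibroblast-loaded nanovials, which reads as pooling after loading, but no label describes that step. If the nanovials were pooled after loading, 2 cells on 1 nanovial would not show as mixed. With 1 library there is no replicate check, and here and below exact intervals cover counting error only.

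The comparison of suspended, sorted and nanovial-loaded MSCs sets the transcriptomes of cells on nanovials against those of cells off them. Sorted and suspended cells were close to each other: the median absolute log2 ratio between sorted and suspended cells was 0.07 over 2392 genes, against 0.02 from counting error alone. Some lists nevertheless lay at the edge of the random lists between sorted and suspended cells, with small medians: mitosis (-0.11, percentile 0.01), glycolysis (0.09, percentile 99.7), DNA replication (0.09, percentile 99.4) and secreted angiogenic factors (-0.05, percentile 1.66). Between nanovial-loaded and sorted cells the median absolute ratio was 0.42 over 2429 genes. Nanovial-loaded cells had higher levels of DNA replication, heat shock and unfolded protein response genes and lower levels of sterol synthesis genes and of several MSC surface markers. Each condition had 1 library, so these are differences between libraries without a test. If the suspended cells did not go through the loading and secretion steps, binding cannot be told apart from time and handling.

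The 10 genes furthest higher in nanovial-loaded cells included the BMP-responsive transcriptional regulators ID3 and ID1, the haem-degrading enzyme HMOX1, the sphingosine kinase SPHK1 and the hyaluronan synthase HAS2. ID3 was at 5.20 counts per 10000 of the summed counts (exact Poisson 95% interval 5.12 to 5.27) against 0.327 (0.307 to 0.348) in sorted cells. Log2 ratios were taken of per-cell means, which were 5.44 against 0.324 for ID3, a ratio of 4.03. HMOX1 was at 1.58 (1.54 to 1.62) against 0.128 (0.116 to 0.142) of the summed counts and had a log2 ratio of 3.39 (means of 1.52 and 0.136). SPHK1, HAS2 and ID1 had log2 ratios of 3.07, 2.97 and 2.53. Others among them were the protease inhibitor TFPI2 (3.13), the lipid chaperone FABP5 (2.58), the secretory granule protein SCG5 (2.60) and the potassium channel KCNMA1 (2.49). In cells of a shared depth range TFPI2 was at 2.24 and FABP5 at 2.05. The 10 furthest lower were led by TXNIP, an inhibitor of thioredoxin, at 0.227 (0.212 to 0.243) against 2.20 (2.15 to 2.25) of the summed counts, with a log2 ratio of -3.25 (means of 0.244 and 2.40). HMGCS1, which makes the sterol precursor HMG-CoA, had a log2 ratio of -2.94, the lipid desaturases SCD and FADS2 -2.58 and -1.96, the aldo-keto reductase AKR1C3 -2.48 and the nuclear RNA NEAT1 -2.17. The p53 target CCNG1 (-2.11), the growth factor receptor PDGFRA (-1.99), YPEL3 (-1.98) and AHNAK2 (-1.98) completed the set. Between sorted and suspended cells the named ratios were smaller, from -0.79 for the ribosomal protein gene RPS29, -0.68 for the phospholipase PLCG2 and -0.65 for the respiratory chain gene NDUFB1 to 0.35 for the actin-binding gene TAGLN, 0.33 for the linker histone gene H1-5 and 0.29 for CCN2.

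Of 21 measured DNA replication genes, 20 were higher by more than 0.5 on the log2 scale in nanovial-loaded than in sorted cells, among them CDC6 (2.85), GINS2 (2.47) and the replicative helicase gene MCM7 (2.19). The list's median ratio, 1.91, lay above all of 10000 random lists matched on mean expression; these are low genes, and it was 1.10 with a pseudocount of 0.1 and 0.28 with means of log values. Mitosis genes had a median of -0.02 over 26 genes at percentile 61.7, and of -0.56 in cells of a shared depth range. All 20 sterol synthesis genes were lower by more than 0.5, with a median of -1.27 below every random list, among them HMGCS1 and SCD with the ratios given above. Heat shock genes had a median of 0.91 (9 of 13 above 0.5, percentile 99.99), with HSPH1 at 1.56 and HSPE1 at 1.26, and genes of the unfolded protein and integrated stress response had 0.52 (12 of 24, percentile 99.9), with PSAT1 at 2.40 and ASNS at 2.30. MSC surface markers had a median of -0.79 (8 of 15 below -0.5, below every random list), with VCAM1 at -3.05, while the integrin ITGA5 was at 0.85. Genes encoded in the mitochondrial genome had a median of -0.65 (9 of 13, percentile 0.01) and HIF targets -0.53 (14 of 26, percentile 0.06), the latter with MXI1 at -1.82 and VEGFA at -0.59. Another 3 HIF targets were higher by more than 0.5, among them ANGPTL4 (0.640 against 0.228 counts per 10000). Pericyte and smooth muscle markers had a median of 0.88 over 4 genes (percentile 99.4), and immediate early genes 0.41 over 19 (percentile 97.6). The medians of the remaining lists lay between percentiles 4.14 (YAP targets, -0.36) and 90.7 (inflammatory cytokines, 0.19). Extracellular matrix genes went both ways, 9 higher and 9 lower by more than 0.5, with the elastin gene ELN at 3.43 and the matrix protease MMP3 at 4.89 at one end and the collagen gene COL12A1 (-1.78) and the proteoglycan DCN (-1.57) at the other.

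**Figure D1:**
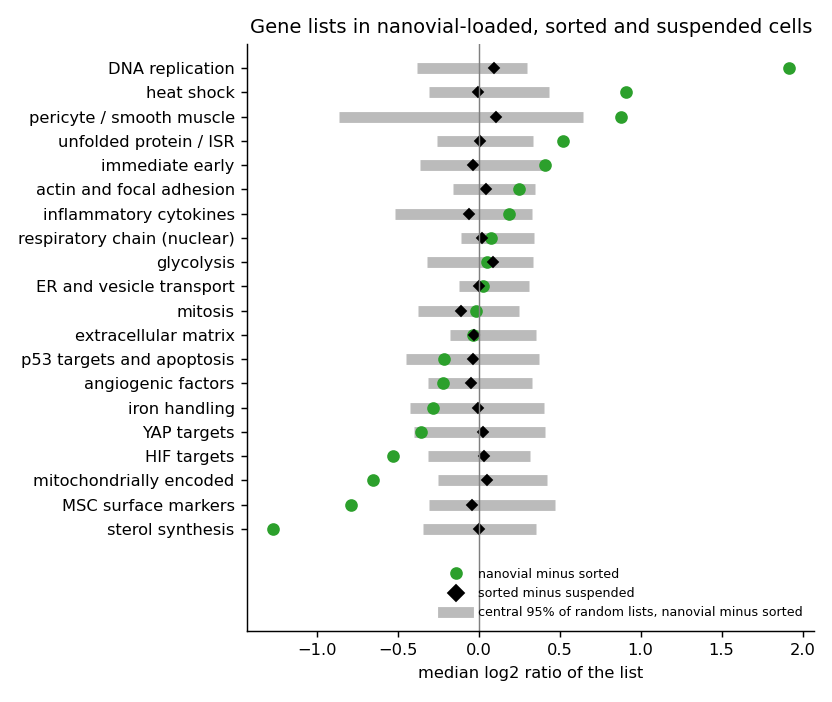
Median log2 ratio of each gene list between nanovial-loaded and sorted cells (circles) and between sorted and suspended cells (diamonds), with the central 95% of 10000 random lists matched on expression as bars. DNA replication lies at 1.91 and sterol synthesis at -1.27 between nanovial-loaded and sorted cells, and every diamond lies within 0.11 of 0.

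The nanovials carried a barcode of their own in this experiment. Its median was 2930 counts in nanovial-loaded cells and 0 in both suspended libraries, where 3.65% of suspended cells (exact binomial interval 3.06 to 4.32) and 3.25% of sorted cells (2.67 to 3.91) had any such count. In the pooled library cells called hypoxic had medians of 60506 and 956 counts of nanovial barcodes 1 and 2. Cells called normoxic had 600 and 62107. The ratio of both barcodes was at least 12.6 in cells called hypoxic and at most 0.0796 in cells called normoxic. The call was deposited beside these barcodes and was presumably made from them. These values then describe the call and do not test it.

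Under deferoxamine the HIF programme was higher with either normoxic SEC-seq library as the control, while the fall of mitotic genes in SEC-seq depended on that control. Of 28 measured HIF targets 27 rose, with a median log2 difference of 2.46, and 18 of 19 glycolysis genes rose, with a median of 1.13. VEGFA mRNA rose 4.74-fold (log2 difference 2.24 ± 0.12, moderated SE, n = 2 experiments, limma, Benjamini-Hochberg adjusted p = 1.25e-07). It rose from 1.19 to 4.67 counts per 10000 in the pooled library (log2 difference 1.96) and from 0.827 to 4.81 in SEC-seq (2.53). Of 26 mitosis genes 25 fell, with a median of -0.82 (-0.98 in the pooled library, -0.70 in SEC-seq). Against normoxic replicate 2 the SEC-seq median was -0.08, with 16 of 26 lower. IL13RA2, the decoy receptor for interleukin 13, was at a log2 difference of 0.02 ± 0.13 (adjusted p = 0.926).

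The comparison used the within-experiment difference of the pooled library and of SEC-seq, where the hypoxic library shares a table with normoxic replicate 1. At an adjusted p of 0.05, limma called 1081 genes higher and 1886 lower of 9402 tested. edgeR on the recovered counts called 1621 higher and 1221 lower, and the median difference of all genes was -0.10 in the main scale and 0.01 in edgeR's. With normoxic replicate 2, which lies in a separate table, as the SEC-seq control, limma called 0 genes, with 782 at an unadjusted p under 0.05 and a VEGFA difference of 2.33 (adjusted p = 0.280). With the mean of both normoxic libraries as the control it called 71 higher and 5 lower. Across 9176 genes, which are not independent replicates, the differences of both experiments had a Spearman rho of 0.718.

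The largest rises were those of the glycolytic regulator PFKFB4 (4.10 ± 0.13), the lipoprotein lipase inhibitor ANGPTL4 (4.05 ± 0.14), MIR210HG, the host transcript of the hypoxia-induced microRNA miR-210 (3.96 ± 0.26), and NDRG1 (3.90 ± 0.09, 14.9-fold, limma adjusted p = 5.61e-10). The moderated SE of MIR210HG stands beside differences of 4.74 in the pooled library and 3.17 in SEC-seq. They were followed by ZP1 (3.71), the carbonic anhydrase CA9 (3.60), ANKRD37 (3.53), the enolase ENO2 (3.50), the lipid droplet protein HILPDA (3.31) and the mitophagy receptor BNIP3 (3.31). The pyruvate dehydrogenase kinase PDK1, which diverts pyruvate from the mitochondrion, rose by 2.98 and the aldolase ALDOC by 2.59. The largest falls were those of the mitotic kinases PLK1 (-2.55 ± 0.12, adjusted p = 3.04e-08) and AURKA (-1.78), the anaphase activator CDC20 (-2.06), the cyclin CCNB1 (-2.01), the spindle protein DLGAP5 (-1.69) and the linker histones H1-5 (-2.21) and H1-1 (-2.10). RAB27B, a vesicle-docking GTPase, fell by 1.72, the interferon-induced GBP1 by 1.71 and the matrix protease MMP3 by 1.66. The 20 genes of largest rise and fall had the same sign in both experiments by the rule that chose them. Of the other single genes fixed beforehand, EPAS1, which encodes HIF-2α, rose by 0.60 (adjusted p = 0.00221) and TERT, the telomerase gene used to immortalise many lines, fell by 0.60 (0.0155). The HIF subunits HIF1A (-0.12) and ARNT (-0.09), the ubiquitin ligase gene VHL (-0.01), the VEGF co-receptors NRP1 (-0.17) and NRP2 (0.06), and the interleukin receptor genes IL13RA1 (0.15) and IL4R (-0.01) did not pass the test.

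Of the 20 lists tested with limma's camera at a preset correlation of 0.01, 10 were higher and 3 lower at an adjusted p of 0.05. None passed with an estimated correlation, where the lowest adjusted p was 0.519. That setting estimates the correlation from 2 differences per gene. Even HIF targets, of which 27 of 28 rose, did not pass it, so it cannot decide for the other lists. HIF targets (adjusted p = 3.25e-37; 27 also rose when adjusted over the list alone) and glycolysis genes (1.56e-18; 18 adjusted over the list alone, with 1 fall) led. Immediate early genes, the first transcribed after a stimulus, rose in 17 of 20 members and fell in 1 (median 0.98, adjusted p = 8.19e-13), among them IER3 (1.85), FOSB (1.38) and ATF3 (2.07). Of 16 inflammatory cytokine genes 11 rose and 2 fell (median 0.84, 2.73e-06), among them CXCL8 (2.53), CSF2 (2.33, but measured in the pooled library only, since in SEC-seq it was at 0.00731 against 0 counts per 10000) and TNFAIP3 (2.22). Of 15 p53 targets 7 rose and 0 fell (median 0.20, 1.42e-04), among them the cell cycle inhibitor CDKN1A (1.89), BBC3 (1.54) and GDF15 (1.32). Mitosis genes were lower (8.19e-13; 25 of 26 fell, also adjusted over the list alone). With normoxic replicate 2 as the control they were lower through the pooled library (median -0.58, camera adjusted p = 0.00293 at the preset correlation and 0.807 at an estimated one). Of 22 DNA replication genes 6 rose and 1 fell (median 0.12, 0.00170), led by the cyclin CCNE2 (1.11), DTL (0.59) and E2F1 (0.57).

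Smaller shifts followed. Of 24 secreted angiogenic factors 10 rose and 4 fell (median 0.32, camera adjusted p = 6.13e-04), with ANGPTL4, CXCL8 and VEGFA in the lead. Of 30 extracellular matrix genes 11 rose and 3 fell (median 0.20, 9.06e-04), among them the collagen cross-linking enzyme LOXL2 (1.41), the collagen COL5A1 (1.36) and TGFBI (1.17). Of 25 genes of the unfolded protein and integrated stress response 8 rose and 1 fell (median 0.17, 0.00580), among them SESN2 (0.90) and DDIT3 (0.62), and of 14 MSC surface markers 3 rose (median 0.13, 0.00534), namely ITGA5 (0.99), CD44 (0.45) and ITGB1 (0.32). Heat shock genes were lower, 9 of 13 falling and 1 rising (median -0.40, 0.00375), among them HSPH1 (-0.78) and HSPA8 (-0.74). Mitochondrially encoded genes were lower too, 8 of 13 falling (median -0.28, 0.0407), among them MT-ND6 (-0.72), MT-ATP6 (-0.56) and MT-ND2 (-0.50). With normoxic replicate 2 as the control the extracellular matrix (median -0.05, adjusted p = 0.0742), MSC surface marker (0.03, 0.0629), heat shock (-0.24, 0.304) and mitochondrially encoded lists (-0.15, 0.903) did not pass. The angiogenic list then had a median of -0.14 with a mean of 0.26. It still passed upward (camera adjusted p = 0.0396), though not with an estimated correlation (0.807). With an estimated correlation the adjusted p of the 13 lists called lay between 0.519 and 0.868. Iron handling genes did not pass as a list (3 of 12 rose, 2 fell; median -0.09 with a mean of 0.07), but its members included the transferrin receptor TFRC (1.77, adjusted p = 1.29e-07) and the ferritin chains FTH1 (-0.39, 0.00576) and FTL (-0.33, 0.0162), of which TFRC was singled out after its values were seen.

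Lists that did not pass were nuclear respiratory chain genes (3 of 33 fell, median -0.04, ATP5MC3 at -0.38), ER translocation and vesicle transport (3 of 39 rose and 1 fell, median -0.03 with a mean of 0.01 and an upward test direction) and actin and focal adhesion (3 of 27 rose, 8 fell, ZYX at -0.49). The others were sterol synthesis (3 of 20 rose, 6 fell, FASN at -0.53), YAP targets (1 of 12 rose, 1 fell, with the tissue factor gene F3 at 2.30) and pericyte and smooth muscle markers (1 of 4 rose, 2 fell, KCNJ8 at -1.58). Of the marker lists too short to test, the adipocyte regulator PPARG fell by 0.87 and the epithelial keratin KRT18 by 0.76, the macrophage-associated CD68 was at 0.29 (adjusted p = 0.0982), and 0 endothelial markers passed the filter. HSPA1A and HSPA1B, the H1 histones and the ferritin genes have close paralogs or pseudogenes whose 3′ reads cannot be told apart with certainty, so their values are uncertain.

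**Figure D2:**
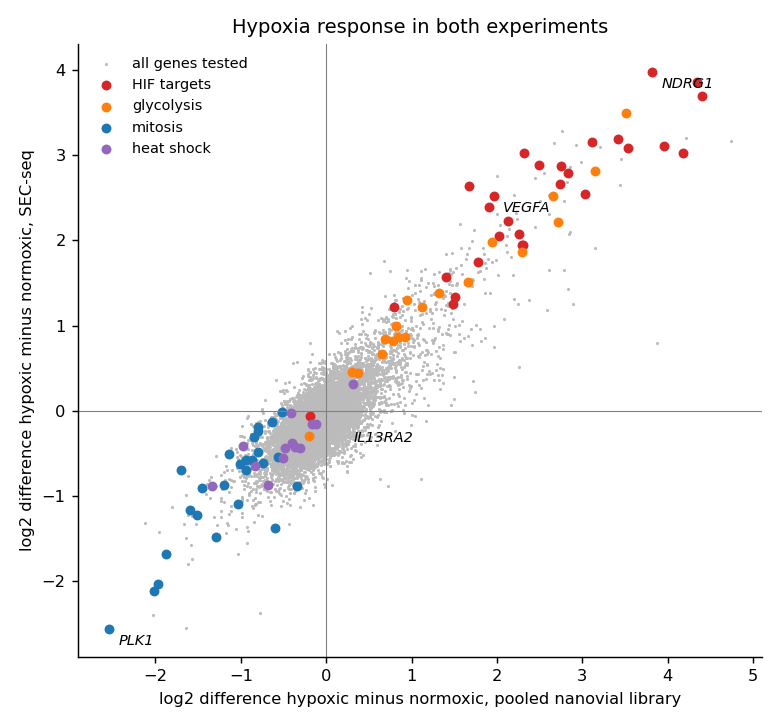
Log2 difference between hypoxic and normoxic cells in the pooled nanovial library (x axis) and in SEC-seq (y axis), 1 point per gene tested, with 4 gene lists coloured. HIF targets and glycolysis genes lie at the upper right (VEGFA at 1.96 and 2.53) and, with normoxic replicate 1 as the SEC-seq control, mitosis genes at the lower left (PLK1 at -2.54 and -2.56).

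Hypoxic cells carried more VEGF-A barcode than normoxic cells of the same table. The median was 1726 barcode counts per cell in the hypoxic library (95% interval of the median from the ranked cells 1661 to 1783) and 967 (925 to 997) in normoxic replicate 1, a ratio of 1.78 (1.67 to 1.93). The ratio was 1.91 per mRNA count and 1.92 in cells matched on mRNA counts in 10 bins, where it was at least 1.64 in every bin. Normoxic replicate 2 had a median of 4105 (3954 to 4290), which makes the hypoxic median 0.420 of it. The normoxic libraries thus differed 4.25-fold, more than the hypoxic library from replicate 1, and their median mRNA counts differed 2.61-fold; they lie in separate tables, and levels set across tables are not comparable in the way levels within a table are. With 1 hypoxic library, and a normoxic library in another table, no test of condition was run on the barcode. Only 1, 0 and 5 cells of normoxic replicate 1, normoxic replicate 2 and the hypoxic library had 0 barcode counts. Within each library cells differed widely, with medians of 2355 and 395 counts in the top and bottom quartile of normoxic replicate 1, 10532 and 1681 in replicate 2, and 4440 and 686 in the hypoxic library. The barcode rose with the cell's mRNA counts, with a Spearman rho of 0.291, 0.330 and 0.381 across cells in that order.

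**Figure D3:**
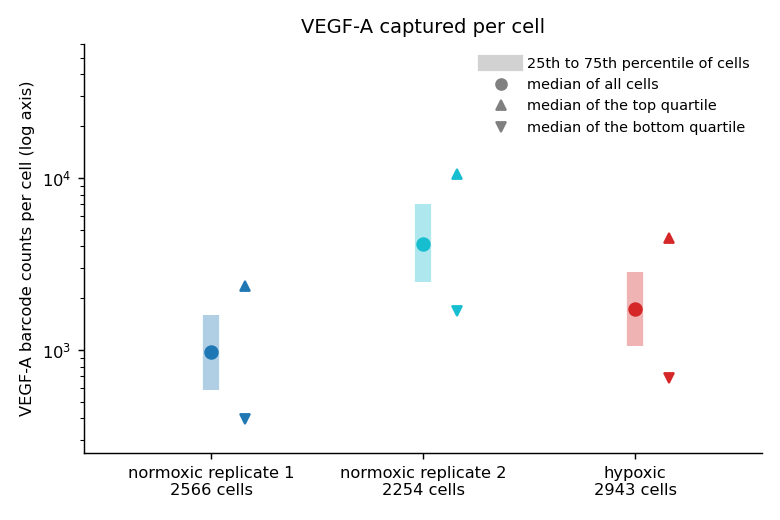
VEGF-A barcode counts per cell (log axis) in the 3 SEC-seq libraries, with the median of all cells (circles), the 25th to 75th percentile (bars) and the medians of the top and bottom quartile (triangles). The hypoxic median, 1726, lies between those of normoxic replicate 1 (967) and normoxic replicate 2 (4105).

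On normalised values, measured VEGFA mRNA went only weakly with the VEGF-A barcode of a cell. VEGFA mRNA was at 0.827 and 0.730 counts per 10000 in normoxic replicates 1 and 2, and such low counts can lower a rho. The barcode also gathers over 12 h of secretion, while the mRNA is read at 1 time. Across cells, normalised VEGFA mRNA and the barcode had a Spearman rho of -0.0193 in normoxic replicate 1, 0.0826 in normoxic replicate 2 and 0.148 in the hypoxic library (mean 0.0704 ± 0.0842, SD, n = 3 libraries). Given total mRNA counts, the partial rho was 0.0502 ± 0.0866, and among cells with VEGFA mRNA it was 0.00503 ± 0.137. Recovered VEGFA counts, which grow with a cell's depth as the barcode does, gave 0.221 ± 0.129. On normalised values IL13RA2 had a higher rho than VEGFA in each library, 0.192, 0.339 and 0.212 (mean 0.248 ± 0.0795), and a partial rho of 0.225. In the hypoxic library the order was the other way on recovered counts (VEGFA 0.355, IL13RA2 0.237) and among cells with the mRNA (VEGFA 0.143, IL13RA2 0.0814). Cells are not replicates, so each rho describes a library.

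**Figure D4:**
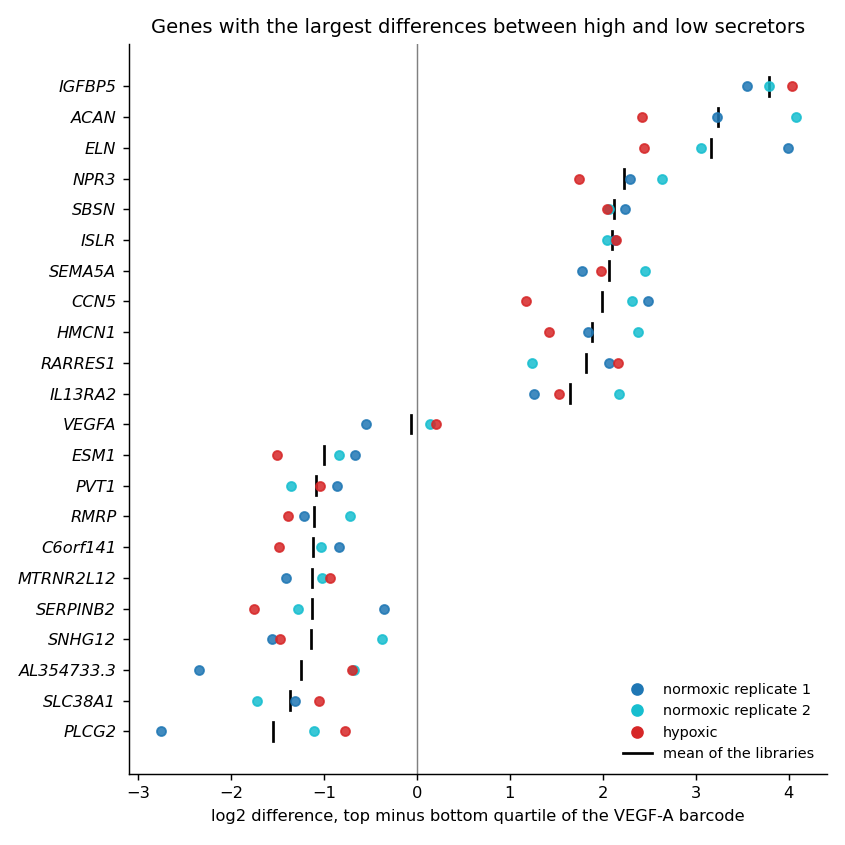
Log2 difference between the top and bottom quartile of the VEGF-A barcode for the 10 genes with the largest rise and fall, IL13RA2 and VEGFA, with a point per library and a bar at their mean. IGFBP5 lies between 3.56 and 4.04, IL13RA2 between 1.26 and 2.17, and VEGFA between -0.55 and 0.20.

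High and low secretors, the top and bottom quartile of the VEGF-A barcode within each library, differed in extracellular matrix, stromal marker and mitochondrial genes, while VEGFA itself did not pass the test. VEGFA was at a log2 difference of -0.07 ± 0.13 (moderated SE, n = 3 libraries, limma adjusted p = 0.739), from -0.55 in normoxic replicate 1 to 0.20 in the hypoxic library. Some cells of low barcode in normoxic replicate 1 had high VEGFA and may contribute to the -0.55. The authors' cluster M2 (71 cells, median mitochondrial share 40.6%) had a median barcode of 441 and VEGFA at 2.59 counts per 10000. The 241 normoxic cells with the barcode prefix of hypoxic cells had 696 and 1.75, against 989 and 0.731 in the other normoxic cells. IL13RA2 rose 3.14-fold in high secretors (1.65 ± 0.15, limma adjusted p = 3.36e-04; 1.26, 2.17 and 1.53 in normoxic replicate 1, normoxic replicate 2 and the hypoxic library). Without the authors' small cluster of highest barcode in each library, which made up 15.2% to 32.0% of the top quartile, it was at 0.50 (adjusted p = 0.0366). Of 30 extracellular matrix genes 18 rose and 2 fell, with a median of 0.42, and all 13 mitochondrially encoded genes fell, with a median of -0.44. The list tests passed at a preset correlation only, and with an estimated one the lowest adjusted p was 0.579.

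The largest rise was that of IGFBP5, which binds insulin-like growth factors (3.79 ± 0.10, 13.9-fold, limma adjusted p = 3.00e-07), from 0.0312 to 0.475 counts per 10000 in normoxic replicate 1, from 0.0899 to 1.37 in replicate 2 and from 0.0489 to 0.957 in the hypoxic library. It was followed by the cartilage proteoglycan ACAN (3.25 ± 0.26, at or near 0 in every bottom quartile, so that its size depends on the pseudocount), elastin (ELN, 3.17 ± 0.23, 8.97-fold), the natriuretic peptide clearance receptor NPR3 (2.23), SBSN (2.12), the stromal surface protein ISLR (2.10), the guidance factor SEMA5A (2.07), the matricellular protein CCN5 (1.99), the basement membrane protein HMCN1 (1.88) and RARRES1 (1.82). The largest falls were those of the signalling phospholipase PLCG2 (-1.55 ± 0.29, adjusted p = 0.0120), the glutamine transporter SLC38A1 (-1.36), the unnamed transcript AL354733.3 (-1.24), the snoRNA host gene SNHG12 (-1.14), the protease inhibitor SERPINB2 (-1.13), MTRNR2L12 (-1.12), C6orf141 (-1.12), RMRP, the RNA of an endoribonuclease that processes ribosomal RNA (-1.11), the non-coding RNA PVT1 (-1.09) and ESM1 (-1.002). By the rule that chose them, all 20 had the same sign in the 3 libraries. Normoxic replicate 1 carried much of the size of PLCG2 and AL354733.3, which were at -0.94 and -0.69 without it. MTRNR2L12 resembles the mitochondrial 16S ribosomal RNA, so its reads cannot be assigned with certainty. Of the other single genes fixed beforehand, NRP2 fell by 0.33 (adjusted p = 0.0415) and VHL by 0.31 (0.0497), and HIF1A (0.03), EPAS1 (-0.09), ARNT (0.01), NRP1 (0.09), IL13RA1 (0.02), IL4R (-0.13) and TERT (-0.16) did not pass.

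Of 9644 genes tested, limma called 665 higher and 985 lower in the top quartile. edgeR on the recovered counts called 1055 higher and 883 lower, and the mean of the deposited log values 1057 and 234. Without normoxic replicate 2, the deepest library, limma called 303 higher and 257 lower. Cells of the top quartile had more mRNA counts (medians of 31470, 86105 and 38666 against 23118, 61746 and 22450 in normoxic replicates 1 and 2 and the hypoxic library) and a lower mitochondrial share (5.47%, 4.13% and 4.68% against 5.74%, 4.95% and 5.12%). With quartiles taken within 10 bins of mRNA counts limma called 1142 higher and 2647 lower, and within bins of mitochondrial share 240 and 125. In each library 1 small cluster of the authors' had the highest median barcode. Without these clusters limma called 383 higher and 484 lower, and IGFBP5 was at 1.63 and ELN at 1.76. Among genes named in this comparison, NRP2, VHL, KDELR1, HMGCS1 and INSIG1 lost the call when either normoxic library was left out, and PFKFB3 when replicate 1 was. DDIT4, STC2, ANPEP, HSPD1, CRIM1, CXCL5 and CXCL8 lost it without replicate 2, and CENPA and ZFP36 without replicate 2 or the hypoxic library. CCNE2, CCNG1 and GAPDH gained it without replicate 1, and KRT18 without the hypoxic library.

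Of 20 lists tested with camera at a preset correlation, 8 were higher and 3 lower in high secretors, and none passed with an estimated correlation, where the adjusted p of all lists lay between 0.579 and 0.997. Extracellular matrix genes led (camera adjusted p = 5.08e-13; 22 rose and 3 fell when adjusted over the list alone), among them ELN, the metalloproteinase inhibitor TIMP3 (1.30) and FBLN1 (1.07). MSC surface markers rose in 6 of 14 members (median 0.22, 3.20e-06; 10 adjusted over the list alone), among them PDGFRB (1.32), ITGA5 (0.36) and ANPEP (0.35, and 0.21 without the hypoxic library). The 4 measured pericyte and smooth muscle markers had a median of 0.59 (0.00853), with rises of NOTCH3 (0.87), ACTA2 (0.62) and CSPG4 (0.56), and the lysosomal protein gene CD68 rose by 0.62. Secreted angiogenic factors had 8 rises and 4 falls among 25 (median 0.15, 9.15e-04), with the chemokine CXCL12 (1.52) and the growth factor FGF7 (1.02) rising. Actin and focal adhesion genes had 6 rises among 27 (median 0.10, 1.18e-04), among them the caveolar protein CAV1 (0.45) and vimentin (VIM, 0.41). The remaining rises were those of ER translocation and vesicle transport (2 of 39, median 0.05, 0.00351), with the ER retrieval receptors KDELR3 (0.66) and KDELR1 (0.25), of sterol synthesis (3 of 20, median 0.05, 0.0119), with SCD (0.40), HMGCS1 (0.33) and INSIG1 (0.31), and of immediate early genes (3 of 20 with 3 falls, median 0.16, 0.0179), with DUSP1 (0.76) and ZFP36 (0.45). Within depth bins the sterol list did not pass (median -0.03, adjusted p = 0.188). The immediate early list had medians of -0.04, 0.49 and 0.01 in normoxic replicates 1 and 2 and the hypoxic library, and did not pass without normoxic replicate 2 (median 0.07, adjusted p = 0.536) or without the cluster of highest barcode (median 0.02, adjusted p = 0.361).

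Mitochondrially encoded genes were lower (camera adjusted p = 1.59e-06, all 13 fell, also adjusted over the list alone), from -0.23 for MT-CO1 to -0.69 for MT-ND4L. The lower mitochondrial share of the top quartile given above is summed over genes of the mitochondrial genome, so it is the same observation. The list median was -0.30 within depth bins (camera adjusted p = 0.0129). It was -0.25 within bins of mitochondrial share (camera adjusted p = 7.06e-04). Those bins group cells by the sum of these same genes, so that value is no independent check. In normoxic replicate 1 the authors' cluster M2 (71 cells) had a median mitochondrial share of 40.6% and a median barcode of 441. Of its cells 5.63% lay in the top quartile. In the hypoxic library (41 cells) these values were 33.3%, 847 and 17.1%. How far such cells carry the fall is open. Mitosis genes were lower (median -0.24, 0.00351), with 5 of 26 falling, among them BUB1B (-0.57), CENPA (-0.50) and CDC20 (-0.44). The hypoxic library carried much of this, with a median of -0.49 against -0.18 and -0.09. Without it CENPA was at -0.33 and CDC20 at -0.24, and the list did not pass (median -0.12, adjusted p = 0.125). Nor did it pass within bins of mitochondrial share (-0.04, adjusted p = 0.700) or without the cluster of highest barcode (-0.10, adjusted p = 0.517). Genes of the unfolded protein and integrated stress response were lower at the threshold (median -0.12, adjusted p = 0.04998), with 5 of 25 falling, among them TRIB3 (-0.96), DDIT3 (-0.81) and SLC7A11 (-0.79), which are stress-induced rather than chaperone genes. That list had a median of 0.02 in the hypoxic library against -0.18 and -0.25 in the normoxic ones, and did not pass within depth bins (adjusted p = 0.259) or without normoxic replicate 1 (0.113) or 2 (0.239). HIF targets did not pass (median and mean -0.06 with an upward test direction, adjusted p = 0.615): 3 of 27 rose and 3 fell, the latter DDIT4 (-0.85, and -1.28 without the hypoxic library), STC2 (-0.69) and PFKFB3 (-0.52, and -0.29 without normoxic replicate 1). The list was higher within depth bins (median 0.11, adjusted p = 0.00275) and passed upward without normoxic replicate 1 (median -0.02, adjusted p = 0.0448). Glycolysis (2 of 19 fell; median 0.03 and mean -0.04; GAPDH at 0.14, adjusted p = 0.0604), nuclear respiratory chain (1 of 33 rose; median -0.01 with an upward test direction; SDHB at -0.18; higher without the cluster of highest barcode, 0.03, adjusted p = 0.0249), DNA replication (0 of 23 passed limma; CCNE2 at -0.31; the list was lower within depth bins, -0.42, adjusted p = 0.00925, and without normoxic replicate 1, -0.20, adjusted p = 0.0374, and higher within bins of mitochondrial share, 0.06, adjusted p = 0.0267), and heat shock (2 of 13 rose, 1 fell; HSPD1 at -0.30, and -0.19 without the hypoxic library) did not pass as lists. Neither did YAP targets (1 of 12 fell, CRIM1 at -0.36), p53 targets (3 of 16 fell; median 0.06 and mean -0.05; CCNG1 at 0.40, adjusted p = 0.0554) and inflammatory cytokines (1 of 14 rose and 3 fell; CXCL5 at -0.75 and CXCL8 at -0.59, and at -0.48 and -0.34 without normoxic replicate 2). That list was lower without normoxic replicate 1 (-0.33, adjusted p = 0.0448). In iron handling, which did not pass either (median -0.05 and mean 0.09), HMOX1, singled out after its values were seen, rose by 1.76 (limma adjusted p = 3.54e-06) and TFRC fell by 0.49. Of the lists too short to test, PECAM1 was at 0.10, PPARG at -0.11, KRT18 at -0.27 and KRT8 at -0.04, and none of these passed.

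**Figure D5:**
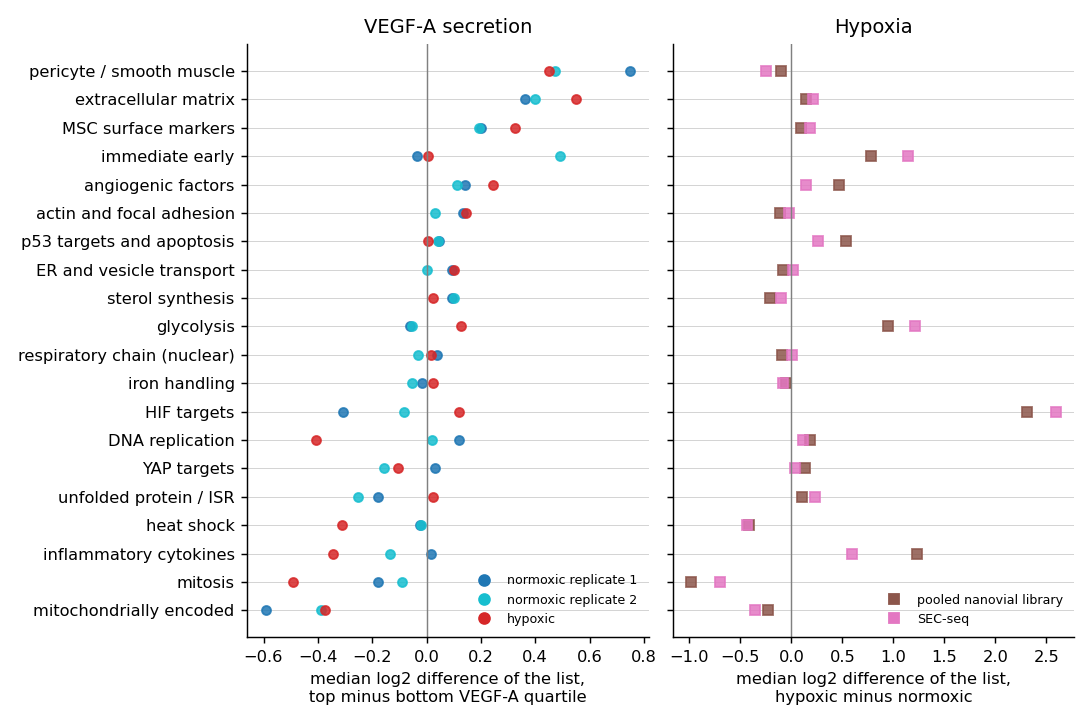
Median log2 difference of each gene list between the top and bottom VEGF-A quartile in the 3 SEC-seq libraries (left) and between hypoxic and normoxic cells in both experiments (right). Extracellular matrix lies between 0.36 and 0.55 in the left panel, and HIF targets, at 2.31 and 2.60 in the right panel, lie between -0.31 and 0.12 in the left.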

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

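Quartiles within bins of mRNA counts were a setting planned beforehand for high against low secretors; their use as a test here, and every other test in this part, were chosen only after the results had been seen.

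The difference between high and low secretors in the hypoxic library was set against that in the normoxic ones. With 1 hypoxic library, and a spread taken from the 2 normoxic libraries alone, the test establishes a difference between conditions for no gene, and the values only describe these libraries. By limma, with 1 residual degree of freedom, 598 genes lay past the threshold between the hypoxic library and the mean of the normoxic ones, 138 with a higher and 460 with a lower difference in the hypoxic library, and within depth bins 0 did. Among the named genes the secretion difference was lower in the hypoxic library for ACAN (by -1.23), ELN (-1.08), NPR3 (-0.71), CCN5 (-1.23), HMCN1 (-0.68), SERPINB2 (-0.94), CXCL12 (-0.62) and CXCL3 (-0.70). ACAN was at 0 in the bottom quartile of the hypoxic library and near 0 in the others, so its value is set by the pseudocount and its level in the top quartiles. It was also lower for the proliferation genes SLBP (-0.39), HELLS (-0.52) and CDC20 (-0.61) and the chaperones HSPD1 (-0.34) and DNAJA1 (-0.45). It was higher for PLCG2 (1.16), DDIT4 (1.30), STC2 (0.90), TRIB3 (0.92), FGF7 (0.42), ANPEP (0.42) and NR4A1 (1.03). DDIT4, a HIF and stress target, was at -1.24 and -1.32 in the normoxic libraries and 0.02 in the hypoxic one. In ACAN (3.24 and 4.08 against 2.42), PLCG2 (-2.76 and -1.11 against -0.78), ELN (3.99 and 3.06 against 2.44), SERPINB2 (-0.36 and -1.27 against -1.76) and HMCN1 (1.84 and 2.38 against 1.42) the normoxic libraries lay further from each other than the nearer of them from the hypoxic one.

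With quartiles taken within bins of mRNA counts, limma called 0 genes (2040 genes at an unadjusted p under 0.05, lowest adjusted p 0.113), while the median absolute difference of the 598 genes was 0.60 against 0.54 and 597 had the same sign (PLCG2, at -0.23, did not). Without the normoxic cells of the other barcode prefix that median was 0.53 and 456 genes were called. Because the 598 genes were picked for this difference and the hypoxic arm is 1 library, neither value excludes unequal depth or those cells, and why the calls were lost within depth bins was not tested. Deferoxamine may act on the link between secretion and these genes, but only 1 hypoxic library had secretion measured, so the condition and that library cannot be told apart.

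Extracellular matrix genes and the leading genes were higher in high secretors. The median of the matrix list was 0.42 in the main result and 0.58 within bins of mRNA counts. It was 0.42 within bins of mitochondrial share and 0.42 without the small cluster of highest barcode. These values argue against each of the 3, taken alone, as the source of the list's median. Single genes of the list may still depend on them. The 10 leading genes had a median of 2.11, which was 2.51 within bins of mRNA counts, 2.03 within bins of mitochondrial share (9 genes passing the filter) and 1.23 without that cluster (8 genes, 7 of them called). These genes were picked for their size, so their values exclude none of the 3 explanations, and how far a small group of cells carries them stays open. No biological explanation was tested.

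Mitosis genes were lower in high secretors by a median of -0.24. Unequal depth argues the other way, since the median was -0.75 within bins of mRNA counts. Within bins of mitochondrial share it was -0.036 and without the cluster of highest barcode -0.10, so either a different mitochondrial share in the quartiles or a small group of cells may account for it. The standard deviation between libraries, 0.21 in the main result and 0.40 and 0.26 in those settings, is close to or above the shift itself. No biological explanation was tested.

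The number of genes that differed between high and low secretors was set against exchanges of top and bottom within single libraries. The real arrangement, 1 of 4, gave 1650 genes and the highest of the others 0, and 4 arrangements are too few for a share under 0.05.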

How the results depend on the processing

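Settings with bins of mitochondrial share, a mitochondrial share under 10%, without the cluster of highest barcode, without cells of the other prefix, on recovered counts for species, those for the hypoxic against normoxic secretion difference, and the other controls for hypoxia lists were chosen only after the results had been seen. Of 2791 alternative values 2255 kept their direction and side of the threshold, or moved within their spread, 288 lost and 51 gained a call, 192 moved and 5 reversed. In the secretion comparison 1260 of 1433 values of single genes and 113 of 140 of lists were unaltered in this sense, and under hypoxia 561 of 686 and 41 of 60. The counts of 665 higher and 985 lower secretion genes became 281 and 268 with a filter of 0.5 (fewer genes tested), 1055 higher with edgeR, 1057 and 234 with means of log values, 232 and 149 with a median split, 1142 and 2647 within depth bins, 1124 and 2663 when a mitochondrial share under 10% was added, 240 and 125 within bins of mitochondrial share, and 383 and 484 without the cluster of highest barcode. Leaving out 1 library gave 303 to 924 higher and 257 to 1310 lower, the lowest without normoxic replicate 2. KRT8 reversed to 0.47 within depth bins and 0.51 with a mitochondrial share under 10% added, and within bins of mitochondrial share the test of DNA replication (0.0620) and mitosis genes (-0.036) turned upward. With an estimated correlation 0 lists were higher and 0 lower in the secretion comparison, against 8 and 3, and 0 and 0 under hypoxia, against 10 and 3. With normoxic replicate 2 as the control 9 hypoxia lists were higher and 1 lower, and the test of nuclear respiratory chain genes turned upward (median 0.034). None of them passed with an estimated correlation, where the lowest camera adjusted p was 0.660. The 1081 higher and 1886 lower hypoxia genes became 332 and 540 with a filter of 0.5, 1221 lower with edgeR, 0 and 0 with normoxic replicate 2 as the control (limma; 782 at an unadjusted p under 0.05) and 71 and 5 with the mean of both normoxic libraries. Leaving out 1 of the 2 hypoxia experiments leaves no residual degrees of freedom, so it was not run. Of the 598 genes with another secretion difference in the hypoxic library 0 were called within depth bins, where 597 kept their sign and the median absolute difference was 0.60 against 0.54. The mean rho of VEGFA was 0.221 on recovered counts, which grow with depth by construction. The median absolute log2 ratio of sorted against suspended cells was 0.0323 with means of log values, that of nanovial-loaded against sorted cells 0.390 with a pseudocount of 0.1, 0.216 with means of log values and 0.391 in the shared depth range, and that against suspended cells 0.4001 and 0.219 with the first 2 of these. Mixed cells were 15.9%, 25.9% and 48.8% at limits of 80%, 90% and 95%, of the deposited, scaled signal, as stricter limits must give, and 12.5%, 19.97% and 31.8% on recovered counts. For the other changes the cause was not tested. Without a filter 1311 of 15855 genes were called in the secretion comparison, with 4302 at an unadjusted p under 0.05.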

Other observations

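The list and the tests in this part were chosen only after the results had been seen. Genes of ribosome biogenesis, which make and process ribosomal RNA, were lower in high secretors: 13 of 26 fell and 0 rose, with a median of -0.37 (calls by limma over all genes). Because the list was put together after the values had been seen, no p of the list is given. Among them the nucleolar protein NCL fell by 0.43, the small-subunit assembly factor PNO1 by 0.67, the RNA helicases DDX21 and DDX10 by 0.54 each and the box C/D factor NOP56 by 0.40, in all 3 libraries, whereas NPM1 was at 0.16. Under hypoxia the same list had a median of -0.39, with 15 falls and 0 rises. A candidate explanation for the secretion difference is the small cluster of highest barcode; without it the median was -0.26, which leaves it open. Within depth bins it was -0.67. The hypoxic library had the largest shifts, as in PNO1 (-1.05 against -0.48 and -0.46 in the normoxic libraries), NOP16 (-0.72 against 0.09 and 0.05) and BOP1 (-0.57 against 0.02 and 0.04).

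The authors' cluster of highest median barcode was small in each SEC-seq library: 137 of 2566 cells in normoxic replicate 1 (5.34%, exact binomial interval 4.50 to 6.28), 211 of 2254 in normoxic replicate 2 (9.36%, 8.19 to 10.6) and 129 of 2943 in the hypoxic library (4.38%, 3.67 to 5.19). Of its cells 97.1%, 85.3% and 86.8% lay in the top quartile. Its median barcode was 4358, 12600 and 5587 against 919, 3790 and 1657 in the other cells. IGFBP5 was at 1.86, 3.31 and 4.62 counts per 10000 there against 0.0482, 0.102 and 0.0946 elsewhere, IL13RA2 at 1.83, 1.83 and 2.22 against 0.234, 0.228 and 0.192, HMOX1 at 10.3, 6.16 and 9.97 against 1.11, 1.02 and 1.495, and the proliferation marker MKI67 at 0.458, 0.231 and 0.260 against 0.917, 0.386 and 0.640. These genes were chosen after their values had been seen, and the clusters of the 2 tables were defined separately by the authors.

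Differences with secretion and differences under deferoxamine were set against each other across the genome, first where no cells were shared. Over 9176 genes, which are not independent replicates, the differences of the pooled hypoxia experiment had a Spearman rho of -0.06 with the secretion differences of normoxic replicate 1, 0.04 with those of normoxic replicate 2 and 0.14 with those of the hypoxic library. Secretion differences of separate libraries had a rho of 0.616, 0.512 and 0.560 with each other. These are 6 of 10 such relations computed, and the others were 0.718 between both hypoxia experiments and 0.02, 0.14 and 0.36 between SEC-seq hypoxia and secretion in normoxic replicates 1 and 2 and the hypoxic library, of which the first and last share cells.

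In the table of both SEC-seq conditions, 241 of 2566 cells annotated as normoxic (9.39%) had the barcode prefix otherwise found on hypoxic cells. Their NDRG1 level was 1.04 counts per 10000, against 0.259 in the other normoxic and 5.402 in the hypoxic cells. Of them 29 lay in clusters the authors named for hypoxia, 161 in clusters labelled N and 51 in clusters labelled M. Over 26 hypoxia genes their median level lay 16.5% of the way from the other normoxic to the hypoxic cells, which argues against most of them being hypoxic cells under a normoxic name; a smaller share of such cells could remain. They had fewer mRNA counts (median 18257 against 28472) and a lower barcode (696 against 989).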
